A study of Rattus norvegicus with 28 samples.

How the data were processed

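The records describe RNA sequencing of 28 libraries of cultured rat cells (strain Crlj:WI per the labels). Per the labels' protocols, ESC were kept on mouse fibroblast feeders with a MEK inhibitor, a GSK3 inhibitor and rat LIF. EpiSC came from post-implantation epiblasts and were kept on feeders with activin A, bFGF, Wnt inhibitors and a ROCK inhibitor, and EpiLC were induced from ESC in suspension with activin A. RNA was isolated with a PicoPure kit and libraries were made with SMART-Seq HT PLUS. The deposited table gives TPM for 23487 genes with versioned Ensembl identifiers. Reads were demultiplexed with bcl2fastq 2.17.1.14 and the genome build is rn6, per the submitters' processing notes. The aligner, the quantifier and the read depth are not given in the sources used here. TPM values keep no depth, so the precision of low values is unknown.

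Each column sums to 1e+06, as checked on the table. Of the 23487 genes, 20717 were above 0 in a library, and the 14588 with at least 1 TPM in at least 2 libraries were tested on log2(TPM + 1). Symbols carried by several identifiers (119) were kept as separate genes. Fgf5 lay below this filter and was not tested.

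Samples were grouped by their titles into 8 groups. All 28 libraries entered a single limma fit (R 4.3.3, limma 3.58.1) with group means, the line (the group or P number where the labels name none) as a random block and a consensus correlation of 0.459 from duplicateCorrelation, followed by eBayes with trend (20 residual and 3.09 prior degrees of freedom). Adjusted p values are Benjamini-Hochberg values from limma over the tested genes, with a threshold of 0.05. The labels do not say whether libraries came from separate cultures, so p measures the spread between these samples. The 11 comparisons were ESC, EpiLC and ESCLC against EpiSC, EpiLC and ESCLC against ESC, the mean of the 3 d3 PGCLC groups against EpiLC and against EpiSC, LC d3ag3 against LC d3, and the 3 pairs of d3 PGCLC groups. Several comparisons share libraries and are not independent.

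The 24 gene lists were core pluripotency, naive pluripotency, formative and primed epiblast, primitive streak and mesendoderm, early primordial germ cell, gonadal and later germ cell, DNA methylation writers and erasers, Wnt target, BMP target, FGF and MAPK response, activin and Nodal target, neuroectoderm, primitive and visceral endoderm, trophoblast, surface and amnion ectoderm, fibroblast and feeder, gonadal somatic, Hox, glycolysis, oxidative phosphorylation, p53 and apoptosis, stress response, cell cycle and sex-linked. Each was tested with cameraPR on the moderated t statistics, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals, and adjusted over all 264 tests. Symbols absent from the table, such as Zfp42, Sox3, Gapdh and Xist, could not be matched. Some genes stand in more than 1 list.

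The text names, for each comparison, the 5 genes with the largest fold change in each direction among those called, without overlap between libraries, with a mean of at least 10 TPM in the higher group and a gene symbol. From each list discussed it names up to 4 called members with the largest fold change, and a set of key genes. This rule, the lists, the comparisons, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise.

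The position of ESCLC was the median over genes of its distance from EpiSC divided by the distance of ESC from EpiSC. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-ratio scaling over the 5363 genes of at least 5 TPM in every library, quantile normalization, removal of mitochondrial and ribosomal protein genes, no line block, a replicate block, a fit of only the groups compared, leaving out libraries and lines, and fry for the lists. GC content was not examined. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

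The procedure was tested on simulated data of 14588 genes. The changed genes were drawn only from genes of higher mean expression, so the shares called do not hold for genes with low values. With 100 genes changed at each size, 97% were called at a log2 fold change of 1 and 97% at 2 between groups of the size of ESC and EpiSC. Here 19 of 213 calls were among genes not changed. For groups of 2 libraries the shares were 73% and 98%, with 14 of 185 calls among genes not changed, and an unchanged comparison gave 0 limma calls. A changed list of 20 genes had an adjusted p of 8.03e-171, and 0 of 50 random lists were called by camera. The simulated noise was independent between genes, so this does not measure false calls for lists whose genes vary together. A line correlation of 0.4 gave 0.373, and a position of 0.8 gave 0.799 by construction.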

Results

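RNA sequencing measured gene expression in 28 libraries of rat cells grown in culture. The labels put 6 libraries in embryonic stem cells (ESC, from 3 lines), 8 in epiblast stem cells (EpiSC, from 4 lines), 2 in epiblast-like cells (EpiLC) and 4 in ESC-like cells (ESCLC). A further 8 libraries came from primordial germ cell-like cells (PGCLC), in groups of 2 that the labels name LC d3, LC d3ag3, LCSC d3 and SC d3 without expanding these names. Values are TPM, which sum to 1e+06 in every library and keep no read depth, so the depth is unknown and no counting interval is given. Between 10815 and 12300 genes stood at 1 TPM or more in a library. Groups are given as mean ± SD over libraries, and fold changes (log2FC, ± SE where given) are on the log2(TPM + 1) scale, which understates the change of genes with low values. An exact 0 in this table is not evidence of absence, because the cytoskeletal actin Actg1 is listed at 0 in all 28 libraries. In the genes given below as largest increases and decreases, no library of one group overlapped the other. For a gene with a 0 in a group, the range over its libraries is given instead of a mean. Counts of list members adjusted over the list alone are given where they differ from those over all genes tested, and equal them elsewhere. For lists, p_est is the camera adjusted p with an estimated correlation, and a list that passed camera and is given without p_est passed with it too.

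Component 1 of the log2(TPM + 1) values held 47.7% of the variance. It placed the ESC and ESCLC libraries between -85.2 and -76.8, the EpiLC libraries at -2.93 and 0.515, and the EpiSC libraries between 63.9 and 78.4. Component 2, with 17.8%, placed the 8 PGCLC libraries between 46.9 and 70.6, and the other libraries between -44.4 and -5.81. Libraries of 1 line correlated across genes with r between 0.977 and 0.990 over 13 pairs, where genes are not independent replicates.

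**Figure D1:**
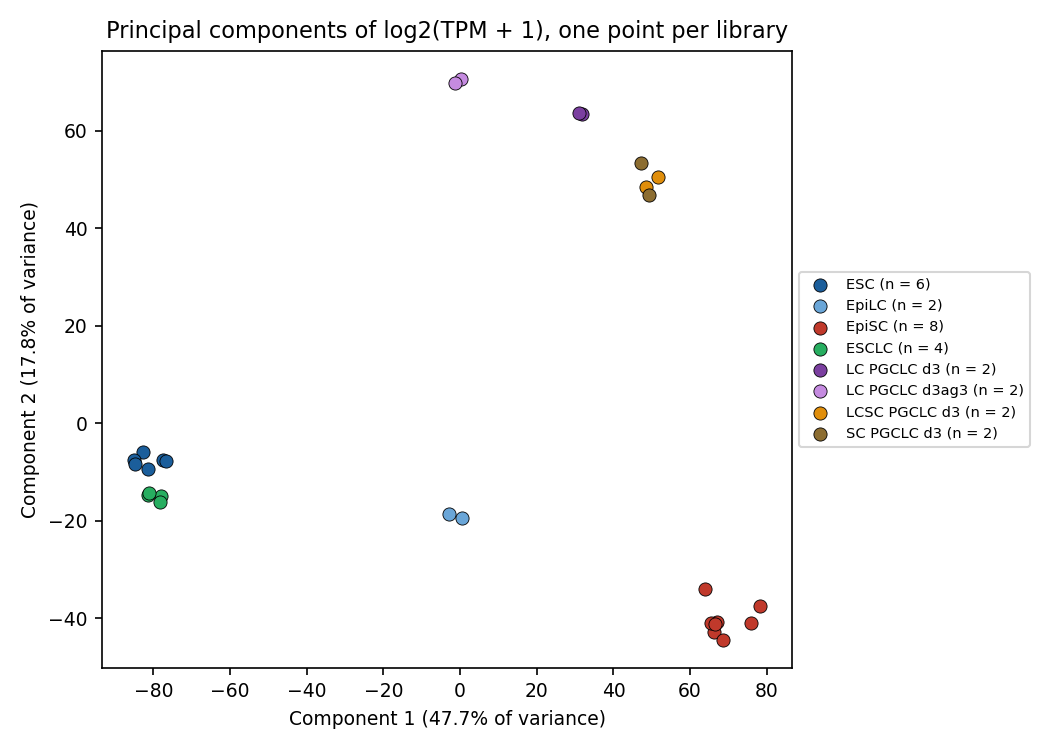
Each point is a library, placed by components 1 (x axis, 47.7% of variance) and 2 (y axis, 17.8%) of log2(TPM + 1), and the colour gives its group. The 8 PGCLC libraries sit above 46.8 on component 2, and the EpiSC libraries lie farthest to the right, between 63.9 and 78.4 on component 1.

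The libraries also fell into a pair of sets by whole groups. Rps6, which encodes a protein of the small ribosomal subunit, stood between 270.2 and 433 TPM in the 16 libraries of EpiSC, ESCLC, LCSC d3 and SC d3. It stood at no more than 6.44e-04 TPM in the 12 libraries of ESC, EpiLC, LC d3 and LC d3ag3. The 100 most abundant genes took 39.5 to 43.3% of the total TPM in the first set and 44.5 to 49.8% in the second. Median-ratio scaling factors were 1.03 to 1.15 and 0.826 to 0.957. Comparisons that cross these sets are named as such below, with their calls under that scaling. Rps6, Rpl39l, Rpl10l, Rps4y2, Ddx3y, Tubb4a, Tuba3a, Ooep, Pramel6, Rhox5, Mageb4 and Gabpb1l belong to multigene families or have closely similar copies, so reads could be split between copies and their values are uncertain.

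The comparison of ESC with EpiSC asked how naive pluripotent cells of the rat differ from cells in the state of the post-implantation epiblast (n = 6 and 8 libraries). Genes of the naive state were far higher in ESC: Dppa5 (1214±100.0 TPM, listed at 0 in every EpiSC library, adjusted p = 2.22e-24) (ENSRNOG00000000199.3), an RNA-binding protein of pluripotent cells, rose with the transcription factor Nanog (424±32.6 against 8.70±3.51 TPM, log2FC 5.54±0.20, adjusted p = 2.77e-17) (ENSRNOG00000008368.7). So did the factors Tbx3 (73.3±9.59 against 0 to 1.32 TPM per library, log2FC 5.83±0.26, adjusted p = 2.58e-15) and Klf2 (184±48.7 against 5.25±4.90 TPM, log2FC 5.25±0.60, adjusted p = 4.73e-08). Genes of the primed epiblast were lower, among them OTX2 (0.842±0.353 against 71.3±7.96 TPM, log2FC -5.31±0.23, adjusted p = 1.81e-15), a homeobox factor of the anterior epiblast, the POU factor Pou3f1 (0.138±0.0525 against 47.4±13.8 TPM, log2FC -5.35±0.18, adjusted p = 1.35e-17) and the de novo DNA methyltransferase Dnmt3b (24.5±6.74 against 384±181 TPM, log2FC -3.73±0.34, adjusted p = 1.50e-09). The shared factors Pou5f1 (410.2±96.2 against 315±71.5 TPM, log2FC 0.38±0.17, adjusted p = 0.0496) and Sox2 (47.9±5.31 against 38.9±6.40 TPM, log2FC 0.30±0.13, adjusted p = 0.0429) were higher. Their log2FC was 0.67 and 0.59 with median-ratio scaling, and the call of Pou5f1 ended with quantile normalization (adjusted p = 0.0604). Other naive factors also rose, namely Klf4 (34.5±5.36 against 3.13±1.75 TPM), Esrrb (28.6±7.39 against 0 to 0.729 TPM per library), Tfcp2l1 (8.16±1.07 against 0.580±0.187 TPM), Prdm14 (5.11±1.81 against 0 to 0.477 TPM per library) and Tcl1a (105±5.41 TPM, listed at 0 in every EpiSC library).

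The largest increases in ESC besides Dppa5 were those of the apolipoprotein Apoc1 (2644±387 against 0 to 14.1 TPM per library), the ribosomal protein paralogue Rpl39l (1381±87.4 against 0 to 1.46 TPM per library), the glutathione peroxidase Gpx2 (1023±232 against 0.612±0.482 TPM) and the oocyte-expressed Ooep (572±148 against 0 to 0.436 TPM per library). The largest decreases were those of the PCNA-associated factor Pclaf (2.01±1.75 against 1058±169 TPM), of Rps6, of the tubulin Tubb4a (0 to 0.290 per library against 127±29.7 TPM), of the imprinted signalling adaptor Grb10 (0.178±0.128 against 112±6.89 TPM) and of the cyclin Ccnd2 (0 to 0.608 per library against 90.3±16.6 TPM). Several genes known from germ cells were higher in ESC, including the helicase Ddx4 (21.3±5.34 against 0 to 0.0307 TPM per library, log2FC 4.43±0.19, adjusted p = 1.15e-15), Tex15 (22.5±3.57 against 0.998±0.244 TPM), a factor of meiosis, Tfap2c (21.1±8.78 against 1.37±2.26 TPM), Dppa3 (9.87±3.42 against 0 to 0.328 TPM per library) and the receptor tyrosine kinase Kit (10.6±3.02 against 4.57±1.56 TPM). The germ cell RNA-binding protein Dazl (2.04±1.19 TPM, listed at 0 in every EpiSC library) rose too. Neither Prdm1 (0 to 0.0478 per library against 0.431±0.709 TPM, adjusted p = 0.116) nor Nanos3 (1.41±0.467 against 1.38±0.885 TPM, adjusted p = 0.802) passed the test, nor did the methylation cofactor Uhrf1 (62.0±32.4 against 47.1±13.8 TPM, adjusted p = 0.550).

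Of the naive pluripotency list, 20 of 24 tested members rose and 3 fell. The test gave camera adjusted p = 6.80e-24. Of the formative and primed epiblast list, 2 of 20 tested members rose and 17 fell (camera adjusted p = 3.71e-05). The exception of largest size was the keratin Krt19 (112±36.2 against 0 to 0.984 TPM per library). For gonadal and later germ cell genes, 16 of 26 tested members rose and 3 fell. The test gave camera adjusted p = 4.30e-04 but p_est = 0.226. For early primordial germ cell genes, 8 of 19 tested members rose and 6 fell. This list had camera adjusted p = 0.00801 but p_est = 0.223. The trophoblast list had camera adjusted p = 0.0363 in the direction of a rise but a median log2 fold change of -0.26, and p_est = 0.259. In this list 3 of 11 rose and 4 fell, led by Cdx2 (log2FC 5.03). The sex-linked list held 3 tested genes, with camera adjusted p = 0.0143 but p_est = 0.215. Of these, Ddx3y (14.3±1.13 TPM, listed at 0 in every EpiSC library) rose while Kdm5d (0 to 11.6 per library against 13.8±4.42 TPM) fell, the latter in the ESC_WT line alone (0 and 0.0224 TPM, against 10.1 to 11.6 in the other ESC libraries), so the list median of -1.46 and mean of 0.18 differ in sign.

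The remaining lists did not pass camera. The core pluripotency list had a median of -0.34 and a mean of 0.75, as 5 of 12 rose and 6 fell (camera adjusted p = 0.0860). Among neuroectoderm genes 1 of 9 rose and 7 fell (camera adjusted p = 0.344). Among primitive and visceral endoderm genes 2 of 12 rose and 3 fell (camera adjusted p = 0.244). Among gonadal somatic genes 0 of 7 rose and 2 fell (camera adjusted p = 0.945). Of the fibroblast and feeder list, 2 of 18 rose and 7 fell (camera adjusted p = 0.877), and its summed TPM was 169±43.2 in ESC against 69.6±26.7 in EpiSC, which were likewise grown on feeders. Of 24 lists, 6 passed camera, and 2 with an estimated correlation. Limma called 9525 of 14588 tested genes, 2764 higher and 6761 lower in ESC, so that 29.0% of calls were higher. This comparison crosses the library sets. Median-ratio scaling gave 3914 higher and 5236 lower (42.8% higher) and moved the median of all genes from -0.30 to -0.09, the level against which single folds are to be read.

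**Figure D2:**
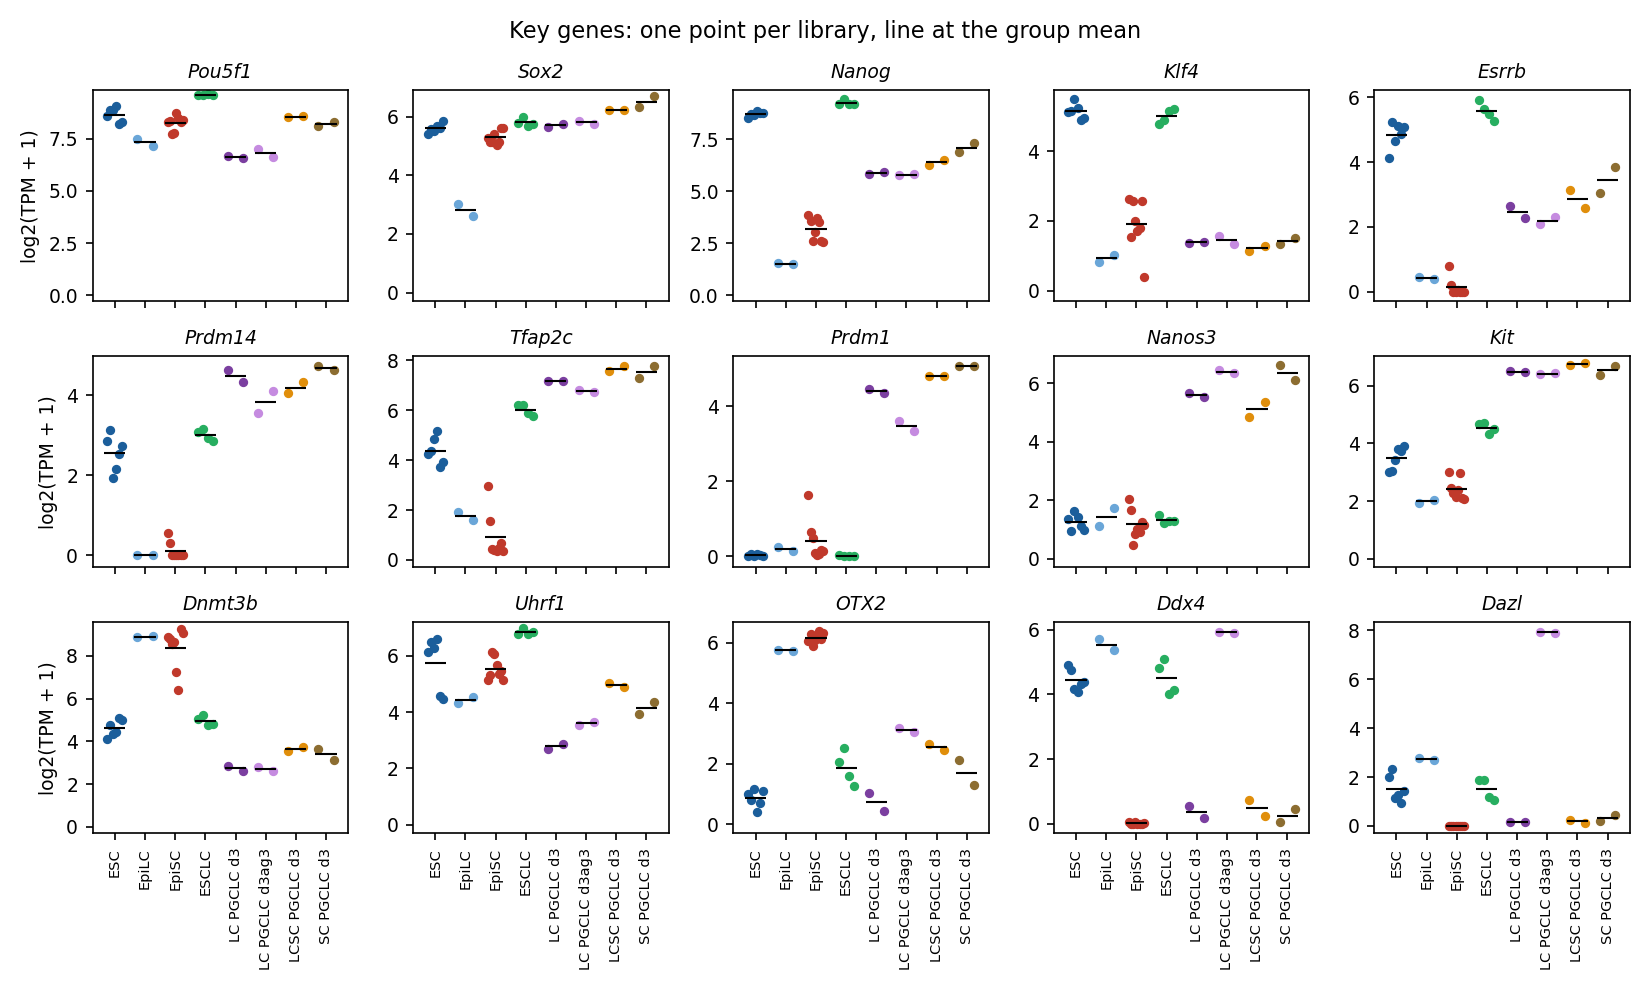
Each panel plots log2(TPM + 1) of a gene (y axis) by group (x axis), with a point per library and a line at the group mean. Nanog lies between 4.99 and 13.5 TPM in EpiSC against 370.1 to 468 TPM in ESC, and Dazl lies at 239.6 and 243 TPM in LC d3ag3 but at no more than 5.88 TPM in any other group.

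The comparison of EpiLC with EpiSC asked how epiblast-like cells made from ESC in culture differ from stem cells derived from the epiblast (n = 2 and 8). The later germ cell genes Ddx4 (45.9±8.17 against 0 to 0.0307 TPM per library, log2FC 5.53±0.28, adjusted p = 4.00e-13), Tex15 (25.4±1.77 against 0.998±0.244 TPM, log2FC 3.73±0.23, adjusted p = 1.50e-11) and Dazl (5.72±0.226 TPM, listed at 0 in every EpiSC library) were higher in EpiLC. Lower were the inhibitors of DNA binding Id1 (7.63±1.15 against 175±44.7 TPM, log2FC -4.32±0.45, adjusted p = 1.08e-07) (ENSRNOG00000021750.5) and Id3 (7.34±0.175 against 103±24.5 TPM, log2FC -3.60±0.22, adjusted p = 1.70e-11), targets of bone morphogenetic protein (BMP) signalling. The pluripotency factors Sox2 (6.11±1.46 against 38.9±6.40 TPM, log2FC -2.49±0.19, adjusted p = 6.84e-10), Nanog (1.85±0.0529 against 8.70±3.51 TPM, log2FC -1.68±0.28, adjusted p = 5.85e-05) and Pou5f1 (162±28.7 against 315±71.5 TPM, log2FC -0.94±0.24, adjusted p = 0.00327) were lower too, although the call of Pou5f1 ended with median-ratio scaling (adjusted p = 0.0505). The methyltransferase cofactor Dnmt3l (49.3±10.6 against 0.253±0.124 TPM, log2FC 5.32±0.16, adjusted p = 2.08e-17) (ENSRNOG00000001212.7) rose. Neither OTX2 (52.6±1.06 against 71.3±7.96 TPM, adjusted p = 0.334) nor Dnmt3b (477±16.0 against 384±181 TPM, adjusted p = 0.413) passed the test.

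The strongest increases were those of Rpl39l (922±130.3 against 0 to 1.46 TPM per library), of Rps4y2, a ribosomal protein gene named as Y-linked (345±11.1 against 0 to 2.27 TPM per library), of the Fc receptor-like Fcrla (256±22.9 against 0 to 0.282 TPM per library), of the X-linked homeobox gene Rhox5 (325±16.0 against 1.34±1.19 TPM) and of the pluripotency-associated Dppa4 (172±2.14 against 0 to 0.406 TPM per library). The strongest decreases were those of Rps6, of Grb10 (0.481±0.0489 against 112±6.89 TPM), of the AP-1 component Fos (1.5±0.178 against 159±119 TPM), of Ccnd2 (1.141±0.384 against 90.3±16.6 TPM) and of Id1. Of the naive list, Dppa5 (22.6±9.78 TPM, listed at 0 in every EpiSC library) and Spp1 (log2FC 3.04) were higher and the cytokine signalling inhibitor Socs3 (log2FC -2.99) lower. Klf4 (0.922±0.190 against 3.13±1.75 TPM, adjusted p = 0.139), Esrrb (0.334±0.0304 against 0 to 0.729 TPM per library, adjusted p = 0.566) and Tfap2c (2.42±0.567 against 1.37±2.26 TPM, adjusted p = 0.194) did not pass the test.

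Of the gonadal and later germ cell list, 18 of 26 tested members rose and 2 fell, with camera adjusted p = 5.21e-24. Of the BMP target list, 0 of 13 tested members rose and 6 fell. Its members had camera adjusted p = 0.0399 but p_est = 0.574. Of the naive list, 7 of 24 tested members rose and 5 fell (camera adjusted p = 3.55e-04), with p_est = 0.0626, and 8 rose and 2 fell with median-ratio scaling. The DNA methylation list gave camera adjusted p = 0.0192 in the direction of a rise, carried by Dnmt3l, while its median was -0.24, and it had p_est = 0.458. In it 2 of 15 rose and 7 fell, but 4 rose and 1 fell with median-ratio scaling. The sex-linked list (camera adjusted p = 4.64e-05) rested on Ddx3y alone. Ddx3y did not follow the Y-linked Eif2s3y, as it was listed at 0 in every EpiSC library, where Eif2s3y stood at 86.3 to 120 TPM. Of the fibroblast and feeder list, 4 of 18 rose and 4 fell, with camera adjusted p = 0.0171 in the direction of a rise, which did not pass with an estimated correlation.

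Of 24 lists, 6 passed camera, and 2 with an estimated correlation. Limma called 6580 genes, 1125 higher and 5455 lower in EpiLC (17.1% higher). Mitochondrial transcripts took 10.9±0.113% of the total TPM in EpiLC against 7.15±0.775% in EpiSC, and the 10 most abundant genes 20.7±0.311% against 17.3±1.35%. This comparison crosses the library sets, and median-ratio scaling gave 1974 higher and 3117 lower (38.8% higher), with the median of all genes at -0.11 instead of -0.36.

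The comparison of EpiLC with ESC followed the induction of epiblast-like cells in activin A from naive cells (n = 2 and 6). The naive factors Nanog (1.85±0.0529 against 424±32.6 TPM, log2FC -7.22±0.29, adjusted p = 7.22e-15) (ENSRNOG00000008368.7), Tbx3 (0.0740±0.00176 against 73.3±9.59 TPM, log2FC -6.10±0.39, adjusted p = 1.84e-11) and Dppa5 (22.6±9.78 against 1214±100.0 TPM, log2FC -5.75±0.24, adjusted p = 7.22e-15) fell steeply. The factors Klf4 (0.922±0.190 against 34.5±5.36 TPM), Esrrb (0.334±0.0304 against 28.6±7.39 TPM), Tfcp2l1 (1.09±0.170 against 8.16±1.07 TPM) and Tcl1a (1.98±0.289 against 105±5.41 TPM) also fell. Genes of the post-implantation epiblast rose, with OTX2 (52.6±1.06 against 0.842±0.353 TPM, log2FC 4.89±0.35, adjusted p = 1.21e-10) (ENSRNOG00000048322.2), Pou3f1 (24.8±2.47 against 0.138±0.0525 TPM, log2FC 4.50±0.27, adjusted p = 6.52e-12) and Dnmt3b (477±16.0 against 24.5±6.74 TPM, log2FC 4.27±0.52, adjusted p = 7.05e-07). Both Pou5f1 (162±28.7 against 410.2±96.2 TPM, log2FC -1.31±0.25, adjusted p = 2.30e-04) and Sox2 (6.11±1.46 against 47.9±5.31 TPM, log2FC -2.79±0.20, adjusted p = 6.95e-11) fell. Germ cell genes changed in either direction, since Ddx4 (log2FC 1.10), Dazl (log2FC 1.23) and the meiotic axis protein Sycp3 (log2FC 2.44) rose while Dppa3 (log2FC -2.82), Tfap2c (log2FC -2.61) and Kit (log2FC -1.50) fell.

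The largest increases were those of Pclaf (475±14.03 against 2.01±1.75 TPM), the homeobox gene Pknox2 (76.7±1.45 against 0.122±0.0712 TPM), Tubb4a (65.6±9.51 against 0 to 0.290 TPM per library), the nucleotide synthesis enzyme Prps2 (68.7±3.01 against 0.556±0.324 TPM) and the nucleotidase domain gene Nt5dc2 (191±1.34 against 3.73±1.16 TPM). The largest decreases were those of Ooep (0.418±0.261 against 572±148 TPM), the PRAME family member Pramel6 (0.159±0.166 against 258±19.0 TPM), Nanog, the keratin Krt19 (0.266±0.0481 against 112±36.2 TPM) and the kinase Sgk1 (0.476±0.135 against 109±7.96 TPM). Prdm14 (listed at 0 in EpiLC, 5.11±1.81 TPM in ESC, adjusted p = 8.16e-08) fell. Uhrf1 (log2FC -1.31) fell, but EpiLC (19.2 and 22.3 TPM) overlapped ESC_N3T (22.7 and 21.1). Neither Prdm1 (0.141±0.0481 against 0 to 0.0478 TPM per library, adjusted p = 0.762) nor Nanos3 (1.74±0.781 against 1.41±0.467 TPM, adjusted p = 0.766) passed.

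Of the naive list, 1 of 24 tested members rose and 18 fell (2 and 19 adjusted over the list alone), with camera adjusted p = 9.09e-22, and of the formative and primed list, 10 of 20 tested members rose and 3 fell (12 and 4 adjusted over the list alone). Here the test gave camera adjusted p = 4.32e-06. Early primordial germ cell genes gave camera adjusted p = 0.0490 but p_est = 0.434. Of these 1 of 19 rose and 6 fell, with the alkaline phosphatase Alpl (log2FC -4.41) and podoplanin, Pdpn (log2FC -2.84), among those that fell. Of the gonadal and later germ cell list, 12 of 26 tested members rose and 1 fell (camera adjusted p = 2.87e-04), with p_est = 0.215. Sohlh2 (log2FC 3.81), a transcription factor of early gametogenesis, and Taf7l (log2FC 1.91) were among those that rose. Of 24 lists, 4 passed camera, and 2 with an estimated correlation. Limma called 4905 genes, 2236 higher and 2669 lower in EpiLC. Mitochondrial transcripts took 8.65±1.18% of the total TPM in ESC, below EpiLC. Of the fibroblast and feeder list, 7 of 18 rose and 2 fell (camera adjusted p = 0.0776), while its summed TPM was 57.8±8.67 in EpiLC against 169±43.2 in ESC. Both groups lie in the same library set.

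The comparison of ESCLC with ESC asked how far ESC-like cells match embryonic stem cells (n = 4 and 6). Of the naive list, 7 of 24 tested members rose and 0 fell (camera adjusted p = 0.750), led by the growth factor Fgf4 (log2FC 1.94) and by Klf2 (log2FC 1.81), Gjb3 (log2FC 1.66) and Nr5a2 (log2FC 1.15). With median-ratio scaling 2 rose and 0 fell, and the calls of Klf2 and Gjb3 ended (adjusted p = 0.107 and 0.0642). The naive factors that did not pass the test included Nanog (615±56.4 against 424±32.6 TPM, adjusted p = 0.0749), Klf4 (31.4±4.79 against 34.5±5.36 TPM, adjusted p = 0.926), Esrrb (47.3±9.23 against 28.6±7.39 TPM, adjusted p = 0.0672) and Tfcp2l1 (8.70±1.82 against 8.16±1.07 TPM, adjusted p = 0.929). Nor did Prdm14 (7.07±0.763 against 5.11±1.81 TPM, adjusted p = 0.116) and Dppa3 (7.33±3.81 against 9.87±3.42 TPM, adjusted p = 0.436). Pou5f1 and the germ cell-associated genes Tfap2c and Kit were higher in ESCLC, with Pou5f1 (787±15.6 against 410.2±96.2 TPM, log2FC 0.97±0.19, adjusted p = 4.83e-04) (ENSRNOG00000046487.2), Tfap2c (65.0±10.4 against 21.1±8.78 TPM, log2FC 1.62±0.41, adjusted p = 0.00422) and Kit (22.4±2.85 against 10.6±3.02 TPM, log2FC 1.02±0.22, adjusted p = 0.00112). The de novo methyltransferase Dnmt3a (48.7±13.2 against 10.97±1.63 TPM, log2FC 1.98±0.16, adjusted p = 1.27e-08) (ENSRNOG00000026649.6), the methylcytosine oxidase Tet2 (38.7±4.41 against 17.5±3.05 TPM, log2FC 1.08±0.15, adjusted p = 2.76e-05) and the histone methyltransferase Ehmt2 (log2FC 1.01) were higher as well. The epiblast factor OTX2 (2.81±1.44 against 0.842±0.353 TPM, log2FC 0.92±0.26, adjusted p = 0.0104) rose from a low level, whereas Sox2 (55.1±5.27 against 47.9±5.31 TPM, adjusted p = 0.385) and Dnmt3b (30.4±4.78 against 24.5±6.74 TPM, adjusted p = 0.649) did not pass the test.

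The strongest increases were those of Rps6, of the tRNA amidation factor Gatc (14.7±6.26 against 0 to 2.46 TPM per library), of the succinate dehydrogenase assembly factor Sdhaf1 (10.5±3.75 against 0 to 1.64 TPM per library), of the AP-1 component Jund (84.2±9.75 against 11.3±2.56 TPM) and of the mitochondrial ribosomal protein Mrpl53 (74.9±12.1 against 0 to 25.1 TPM per library). The call of Mrpl53 ended with median-ratio scaling (adjusted p = 0.0515). The largest decreases were those of the tight junction claudin Cldn5 (0 to 1.40 per library against 12.8±3.24 TPM), of MGC105649 (50.4±11.8 against 426±119.9 TPM), of Faxc (3.01±0.409 against 26.5±16.4 TPM), of the collagen receptor Ddr2 (1.78±0.481 against 16.4±6.83 TPM) and of the LIM protein Crip1 (97.5±19.0 against 507±185 TPM).

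Of the DNA methylation list, 8 of 15 tested members rose and 0 fell. The test for the list gave camera adjusted p = 0.0111 but p_est = 0.412, and 3 rose and 0 fell with median-ratio scaling, which ended the call of Uhrf1 (log2FC 1.09) (adjusted p = 0.0832). Of FGF and MAPK response genes, 0 of 17 tested members rose and 2 fell, with camera adjusted p = 0.0111 in the direction of a fall but p_est = 0.259, and the ETS factor Etv4 (log2FC -1.24) and the signalling inhibitor Spry1 (log2FC -0.44) were lower. Of the Wnt targets Sp5 (log2FC -0.89) and Axin2 (log2FC -0.35), or -0.54 with median-ratio scaling, were lower (camera adjusted p = 0.0267, and p_est = 0.446), and 0 of 12 rose and 2 fell (0 and 0 adjusted over the list alone). Of the oxidative phosphorylation list, 7 of 24 rose and 7 fell (8 and 7 adjusted over the list alone). It had camera adjusted p = 0.0873 and p_est = 0.683. With median-ratio scaling 2 rose and 13 fell (camera adjusted p = 1.55e-05 for a fall, p_est not computed).

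Of 24 lists, 3 passed camera, and 0 with an estimated correlation. Limma called 4380 genes, 3869 higher and 511 lower in ESCLC (88.3% higher). Mitochondrial transcripts took 5.81±1.48% of the total TPM in ESCLC, and the 10 most abundant genes 14.8±0.893% against 17.3±0.981% in ESC. This comparison crosses the library sets, and median-ratio scaling gave 1569 higher and 1185 lower (57.0% higher), with the median of all genes at 0.01 instead of 0.19.

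The comparison of ESCLC with EpiSC set the same ESC-like cells against epiblast stem cells (n = 4 and 8). The naive genes that mark ESC were high in ESCLC, as Nanog (615±56.4 against 8.70±3.51 TPM, log2FC 6.06±0.21, adjusted p = 1.81e-17) (ENSRNOG00000008368.7) and Klf2 (619.9±25.2 against 5.25±4.90 TPM, log2FC 7.05±0.63, adjusted p = 1.05e-09) rose. Tbx3 (145±24.8 against 0 to 1.32 TPM per library, log2FC 6.76±0.28, adjusted p = 5.22e-16), Esrrb (47.3±9.23 against 0 to 0.729 TPM per library, log2FC 5.41±0.27, adjusted p = 1.83e-14) and Klf4 (31.4±4.79 against 3.13±1.75 TPM, log2FC 3.13±0.38, adjusted p = 1.43e-07) followed, as did Dppa5 (1104±88.7 TPM, listed at 0 in every EpiSC library) and Tcl1a (104±9.26 TPM, listed at 0 in every EpiSC library). Primed epiblast genes fell, with OTX2 (2.81±1.44 against 71.3±7.96 TPM, log2FC -4.39±0.25, adjusted p = 2.18e-13), Pou3f1 (0.802±0.403 against 47.4±13.8 TPM, log2FC -4.76±0.19, adjusted p = 3.91e-16) and Dnmt3b (30.4±4.78 against 384±181 TPM, log2FC -3.43±0.37, adjusted p = 1.97e-08). Pou5f1 (787±15.6 against 315±71.5 TPM, log2FC 1.35±0.18, adjusted p = 4.67e-07) and Sox2 (55.1±5.27 against 38.9±6.40 TPM, log2FC 0.49±0.14, adjusted p = 0.00354) rose. The germ cell-associated Tfap2c (log2FC 5.09), Kit (log2FC 2.08), Ddx4 (log2FC 4.42) and Dppa3 (log2FC 2.79) rose as well, while Nanos3 (1.52±0.210 against 1.38±0.885 TPM, adjusted p = 0.618) did not pass the test.

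The largest increases besides Dppa5 were those of Apoc1 (3303±1108 against 0 to 14.1 TPM per library), Rpl39l (1439±84.0 against 0 to 1.46 TPM per library), Ooep (627±135 against 0 to 0.436 TPM per library) and Pramel6 (482±191 TPM, listed at 0 in every EpiSC library). The strongest decreases were those of Pclaf (0.608±0.370 against 1058±169 TPM), Tubb4a (0.0791±0.0440 against 127±29.7 TPM), Grb10 (0.192±0.102 against 112±6.89 TPM), Ccnd2 (0 to 0.455 per library against 90.3±16.6 TPM) and Phlda1 (0.560±0.224 against 106±54.6 TPM).

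Of the naive list, 20 of 24 tested members rose and 2 fell, with camera adjusted p = 1.16e-23, and of the formative and primed list, 3 of 20 tested members rose and 15 fell. Its members had camera adjusted p = 3.55e-04. Core pluripotency genes gave camera adjusted p = 0.0363 but p_est = 0.467, with a median of -0.01 and a mean of 1.11. Among them 5 of 12 rose and 4 fell, as Dppa4 (log2FC 6.08) and the Nodal coreceptor Tdgf1 (log2FC 4.27) rose and the RNA-binding Lin28a (log2FC -3.35) fell. Of the FGF and MAPK response list, 5 of 17 tested members rose and 10 fell. The test gave camera adjusted p = 0.0141 in the direction of a fall but p_est = 0.274, and the phosphatase Dusp6 (log2FC -5.04) and Spry1 (log2FC -4.53) fell. Of the DNA methylation list, 6 of 15 tested members rose and 6 fell (6 and 7 adjusted over the list alone). This list had camera adjusted p = 0.00886 in the direction of a rise but p_est = 0.386: Dnmt3l (log2FC 7.42) and Tet2 (log2FC 4.78) rose while Tdg (log2FC -3.09) fell. Of early primordial germ cell genes, 9 of 19 rose and 6 fell (camera adjusted p = 0.00595 but p_est = 0.215), and of the gonadal and later ones, 16 of 26 rose and 2 fell (camera adjusted p = 0.00133 but p_est = 0.284). Of 24 lists, 8 passed camera, and 2 with an estimated correlation. Limma called 8803 genes, 3733 higher and 5070 lower in ESCLC, and with median-ratio scaling 3880 and 4875. Both groups lie in the same library set.

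The position of ESCLC from EpiSC (0) to ESC (1) was measured over the 4147 genes that differed at least 2-fold between these. The mean was 0.948±0.0212 (SD, n = 4), at 0.931 and 0.929 in P2, 0.966 in P5 and 0.967 in P6. ESC lies in the other library set from EpiSC and ESCLC, and median-ratio scaling gave 0.980. Genes chosen on some lines and measured on the rest gave 0.959 and 0.942.

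The comparison of PGCLC with EpiLC set the germ cell-like cells of LC d3, LCSC d3 and SC d3, weighted equally, against the epiblast-like state (n = 6 and 2). The regulators of primordial germ cell fate rose, with Tfap2c (179±34.9 against 2.42±0.567 TPM, log2FC 5.71±0.55, adjusted p = 1.37e-08) (ENSRNOG00000005246.6), Prdm1 (26.6±5.55 against 0.141±0.0481 TPM, log2FC 4.57±0.32, adjusted p = 9.14e-11) (ENSRNOG00000000323.7) and Nanos3 (54.9±24.6 against 1.74±0.781 TPM, log2FC 4.27±0.35, adjusted p = 1.04e-09). So did Kit (95.7±10.5 against 2.96±0.154 TPM, log2FC 4.60±0.29, adjusted p = 1.96e-11) and Prdm14 (21.2±3.83 TPM, listed at 0 in every EpiLC library, adjusted p = 1.10e-11). The pluripotency factors Nanog (93.2±39.2 against 1.85±0.0529 TPM, log2FC 4.95±0.29, adjusted p = 7.81e-12) and Sox2 (71.9±19.3 against 6.11±1.46 TPM, log2FC 3.33±0.20, adjusted p = 5.72e-12) rose. Pou5f1 (256±128 against 162±28.7 TPM, adjusted p = 0.145) did not pass, at 102 and 93.9 TPM in LC d3 but 275 to 383 in LCSC d3 and SC d3. The DNA methyltransferases fell, with Dnmt3b (8.99±3.05 against 477±16.0 TPM, log2FC -5.64±0.52, adjusted p = 8.14e-09) and Dnmt3a (2.67±1.26 against 169±2.86 TPM, log2FC -5.61±0.21, adjusted p = 2.67e-15), as did the epiblast factor OTX2 (log2FC -4.08). BMP targets rose as a group, led by the homeobox genes Msx2 (log2FC 5.59) and Msx1 (log2FC 5.18) and by Id3 (log2FC 5.55). The later germ cell genes Ddx4 (log2FC -5.18), Dazl (log2FC -2.53) and Sohlh2 (log2FC -4.80) fell.

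The strongest increases besides Tfap2c and Msx2 were those of the tetraspanin Tspan8 (204±34.9 against 0.510±0.0912 TPM), the proteasome activator Psme1 (738±101 against 9.84±2.14 TPM) and the antigen-loading factor Tapbp (153±23.4 against 2.09±1.57 TPM). The largest decreases besides Dnmt3b were those of the protease inhibitor Wfdc15a (listed at 0 in every PGCLC d3 library, 149±32.0 TPM in EpiLC), the cytochrome c oxidase subunit Cox7b2 (0 to 20.8 per library against 147±25.3 TPM), Fcrla (3.67±0.957 against 256±22.9 TPM) and Rpl39l (16.1±3.99 against 922±130.3 TPM). Esrrb (log2FC 2.51) rose and Tfcp2l1 (log2FC -0.55) fell. The rise of Dppa3 (log2FC 1.53) did not pass with median-ratio scaling (adjusted p = 0.0564), and neither Klf4 (1.55±0.222 against 0.922±0.190 TPM, adjusted p = 0.580) nor Uhrf1 (17.7±11.1 against 20.8±2.21 TPM, adjusted p = 0.410) passed the test. Uhrf1 ran from 5.49 TPM in LC d3 to 31.9 in LCSC d3.

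Of the early primordial germ cell list, 15 of 19 tested members rose and 2 fell. The test gave camera adjusted p = 1.35e-07. Of the BMP target list, 13 of 13 tested members rose and 0 fell. Here the test gave camera adjusted p = 3.59e-16. The formative and primed list fell (camera adjusted p = 3.55e-07), and 6 of 20 rose and 10 fell. The DNA methylation list fell as well (camera adjusted p = 4.94e-08), and 3 of 15 rose and 6 fell. Of the gonadal and later germ cell list, 2 of 26 tested members rose and 18 fell. Its members had camera adjusted p = 1.34e-15. Wnt targets had camera adjusted p = 3.65e-04 but p_est = 0.162. In this list 9 of 12 rose and 1 fell (10 and 1 adjusted over the list alone), including the mesoderm factor Tbxt (log2FC 4.73) and the Wnt inhibitor Notum (log2FC 3.32).

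Primitive streak and mesendoderm genes had camera adjusted p = 0.0180 but p_est = 0.643. Of these 12 of 21 rose and 1 fell (13 and 1 adjusted over the list alone), with Fgf8 (log2FC 3.66) and Wnt5a (log2FC 3.56) among those that rose. Trophoblast genes had camera adjusted p = 0.0171 but p_est = 0.206. Among them 7 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), including Hand1 (log2FC 2.96) and Gata3 (log2FC 2.80). Glycolysis genes had camera adjusted p = 0.00492 but p_est = 0.644. In this list 1 of 17 rose and 7 fell, with the phosphofructokinase Pfkm (log2FC -2.85) and the glucose transporter Slc2a1 (log2FC -1.53) lower. The groups differed, with a median log2FC over the list of 1.76 for SC d3 and 1.65 for LCSC d3 against LC d3, and Bnip3, the 1 that rose, did not pass with LC d3 alone (log2FC -0.27, adjusted p = 0.853). Of fibroblast and feeder genes, 3 of 18 rose and 6 fell (camera adjusted p = 0.00498 but p_est = 0.434).

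Of 24 lists, 11 passed camera, and 5 with an estimated correlation. Limma called 6673 genes, 5100 higher and 1573 lower in PGCLC (76.4% higher), and median-ratio scaling gave 3469 and 2490 (58.2% higher), with the median of all genes at 0.08 instead of 0.29. LCSC d3 and SC d3 lie in the other library set from EpiLC, so the comparison was also made with LC d3 alone, chosen after the data were seen. That gave 3040 genes higher and 1682 lower, of which 4235 carried the same call.

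The comparison of PGCLC with EpiSC set the same 3 groups against epiblast stem cells (n = 6 and 8). The germ cell regulators rose from low levels in EpiSC, with Tfap2c (179±34.9 against 1.37±2.26 TPM, log2FC 6.57±0.36, adjusted p = 4.14e-13) (ENSRNOG00000005246.6), Nanos3 (54.9±24.6 against 1.38±0.885 TPM, log2FC 4.52±0.23, adjusted p = 1.40e-13) and Prdm1 (26.6±5.55 against 0.431±0.709 TPM, log2FC 4.35±0.21, adjusted p = 5.73e-14). The same held for Kit (95.7±10.5 against 4.57±1.56 TPM, log2FC 4.16±0.19, adjusted p = 2.80e-14) and Prdm14 (21.2±3.83 against 0 to 0.477 TPM per library, log2FC 4.35±0.18, adjusted p = 4.61e-15). Nanog (93.2±39.2 against 8.70±3.51 TPM, log2FC 3.27±0.20, adjusted p = 1.67e-12) and Sox2 (71.9±19.3 against 38.9±6.40 TPM, log2FC 0.84±0.13, adjusted p = 8.01e-06) rose too, and Pou5f1 (256±128 against 315±71.5 TPM, log2FC -0.48±0.17, adjusted p = 0.0205) fell, a direction that turned when LCSC d3 and SC d3 alone were taken (log2FC 0.11, adjusted p = 0.704). The methyltransferases Dnmt3a (2.67±1.26 against 96.5±10.01 TPM, log2FC -4.81±0.14, adjusted p = 1.27e-17) (ENSRNOG00000026649.6) and Dnmt3b (8.99±3.05 against 384±181 TPM, log2FC -5.10±0.34, adjusted p = 1.63e-11) and the methylation cofactor Uhrf1 (log2FC -1.57) fell. The BMP ligand Bmp4 (log2FC 4.31) and the BMP targets Msx2 (log2FC 5.37) and Msx1 (log2FC 4.57) rose. Neither Ddx4 (0.302±0.237 against 0 to 0.0307 TPM per library, adjusted p = 0.139) nor Klf4 (1.55±0.222 against 3.13±1.75 TPM, adjusted p = 0.211) passed the test.

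The largest increases besides Tfap2c and Msx2 were those of Tspan8 (204±34.9 against 2.27±3.33 TPM), Apoc1 (106±24.3 against 0 to 14.1 TPM per library) and Shisal2b (45.3±10.9 against 0 to 0.738 TPM per library). The largest decreases besides the methyltransferases were those of the gap junction protein Gja1 (5.14±3.74 against 154±31.6 TPM), the neuronal phosphoprotein Crmp1 (1.04±0.356 against 52.7±19.6 TPM) and OTX2 (2.65±2.00 against 71.3±7.96 TPM).

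Of the early primordial germ cell list, 14 of 19 tested members rose and 3 fell (14 and 4 adjusted over the list alone), with camera adjusted p = 2.53e-16, and of the formative and primed list, 2 of 20 tested members rose and 15 fell. The test gave camera adjusted p = 1.00e-12. Of the naive list, 11 of 24 tested members rose and 2 fell, with camera adjusted p = 4.32e-06, among them the connexin Gjb3 (log2FC 4.81) and the factors Klf5 (log2FC 3.89) and Gbx2 (log2FC 3.48). BMP targets (camera adjusted p = 1.84e-12), Wnt targets (camera adjusted p = 1.28e-06) and trophoblast genes (camera adjusted p = 7.36e-05) rose. Among BMP targets 12 of 13 rose and 0 fell, and among Wnt targets 11 of 12 rose and 0 fell. Among trophoblast genes 9 of 11 rose and 0 fell.

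Primitive streak genes had camera adjusted p = 8.21e-04 but p_est = 0.452. Of these 11 of 21 rose and 3 fell (12 and 3 adjusted over the list alone), led by Tbxt (log2FC 4.27). Hox genes had camera adjusted p = 3.22e-04 but p_est = 0.216. Among them 12 of 15 rose and 0 fell, led by Hoxd9 (log2FC 2.66) and Hoxd8 (log2FC 1.67). The groups differed, as Hoxd9 stood at 29.9 TPM in SC d3 and 11.3 in LCSC d3 but at 0.0885 in LC d3. Glycolysis genes had camera adjusted p = 3.47e-04 but p_est = 0.521. In this list 0 of 17 rose and 15 fell, including hexokinase, Hk1 (log2FC -2.05), and the triose phosphate isomerase Tpi1 (log2FC -1.61), which stood at 47.8 TPM in LC d3 against 264 in SC d3 and 260.1 in LCSC d3. Of the DNA methylation list, 2 of 15 rose and 8 fell (3 and 11 adjusted over the list alone) (camera adjusted p = 3.22e-04 but p_est = 0.201). Surface and amnion ectoderm genes had camera adjusted p = 0.0111 but p_est = 0.215. Of these 4 of 9 rose and 1 fell, including Dlx3 (log2FC 1.97) and Dlx5 (log2FC 1.70). Of 24 lists, 11 passed camera, and 6 with an estimated correlation. Limma called 7140 genes, 3330 higher and 3810 lower in PGCLC, and 3570 and 3609 with median-ratio scaling. LC d3 lies in the other library set from EpiSC, and with LCSC d3 and SC d3 alone, a choice made after the data were seen, 3298 genes were higher and 2684 lower, of which 5625 carried the same call.

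The comparison of LC d3ag3 with LC d3 set a further PGCLC state against its d3 counterpart (n = 2 and 2). Genes of later germ cells rose steeply, with Dazl (241±2.58 against 0.106±0.00460 TPM, log2FC 7.78±0.35, adjusted p = 2.70e-13) (ENSRNOG00000023474.5) and Ddx4 (59.5±0.930 against 0.292±0.233 TPM, log2FC 5.56±0.35, adjusted p = 1.00e-10) (ENSRNOG00000026686.6). Others were the kinase Stk31 (57.97±0.437 against 0.270±0.00925 TPM, log2FC 5.54±0.36, adjusted p = 1.54e-10) and Sohlh2 (18.4±0.339 against 0 to 0.0638 TPM per library, log2FC 4.24±0.30, adjusted p = 4.03e-10). The early germ cell regulators did not pass the test, with Tfap2c (108±4.15 against 146±0.0184 TPM, adjusted p = 0.801), Prdm1 (10.2±1.51 against 20.2±1.20 TPM, adjusted p = 0.128), Prdm14 (13.5±3.99 against 21.5±3.20 TPM, adjusted p = 0.229), Nanos3 (84.0±5.44 against 47.8±3.61 TPM, adjusted p = 0.262) and Kit (84.9±1.68 against 88.6±1.68 TPM, adjusted p = 0.977). The mesoderm factors Tbxt (3.21±0.271 against 31.3±3.58 TPM, log2FC -2.94±0.44, adjusted p = 4.62e-05), Wnt5a (0.589±0.00660 against 16.2±1.34 TPM, log2FC -3.44±0.53, adjusted p = 6.69e-05) and Fgf8 (1.36±0.243 against 25.2±2.47 TPM, log2FC -3.47±0.76, adjusted p = 0.00283) fell. So did the BMP target Id2 (log2FC -2.92) and the Nodal pathway inhibitors Lefty1 (log2FC -3.40) and Lefty2 (log2FC -3.99). OTX2 (7.64±0.570 against 0.690±0.470 TPM, log2FC 2.38±0.43, adjusted p = 4.53e-04) rose instead.

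The strongest increases besides Dazl were those of Fcrla (394±15.4 against 3.68±0.781 TPM), the testis-enriched Pxt1 (286±27.9 against 4.58±3.23 TPM), the testis tubulin Tuba3a (84.7±2.32 against 0.593±0.0204 TPM) and the transposon control gene Tex19.1 (68.8±2.39 against 0.423±0.119 TPM). The strongest decreases were those of the neurofilament Nefm (0.0856±0.0645 against 21.6±4.88 TPM), the immunoproteasome subunit Psmb10 (1.74±0.333 against 55.2±4.17 TPM), Bex2 (2.60±1.40 against 65.2±7.19 TPM), the cytokine Il15 (0 to 0.936 per library against 23.8±6.11 TPM) and the protease Tmprss2 (0.0360±0.0323 against 16.4±2.39 TPM). The pluripotency factors Pou5f1 (114±22.6 against 97.7±5.48 TPM, adjusted p = 0.795), Sox2 (54.9±3.36 against 51.1±2.77 TPM, adjusted p = 0.894) and Nanog (54.5±1.66 against 57.7±2.92 TPM, adjusted p = 0.961) did not pass the test.

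Of the gonadal and later germ cell list, 21 of 26 tested members rose and 1 fell (23 and 2 adjusted over the list alone). Here the test gave camera adjusted p = 1.18e-97. Of the BMP target list, 0 of 13 tested members rose and 8 fell (0 and 10 adjusted over the list alone) (camera adjusted p = 2.67e-09). Of the FGF and MAPK response list, 0 of 17 tested members rose and 10 fell (camera adjusted p = 9.76e-06), including Phlda1 (log2FC -3.54) and Dusp4 (log2FC -2.36). Activin and Nodal targets (camera adjusted p = 3.22e-04) and trophoblast genes (camera adjusted p = 3.22e-04) fell. Among the former 1 of 12 rose and 7 fell, and among the latter 0 of 11 rose and 6 fell, with the keratins Krt8 (log2FC -3.10) and Krt18 (log2FC -2.47) lower.

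Glycolysis genes had camera adjusted p = 3.55e-04 but p_est = 0.521. Among them 6 of 17 rose and 0 fell (11 and 1 adjusted over the list alone), with the hexokinase Hk2 (log2FC 1.98) and Tpi1 (log2FC 1.54) higher. Stress response genes had camera adjusted p = 0.0384 but p_est = 0.458. In this list 0 of 16 rose and 6 fell (1 and 6 adjusted over the list alone), including the asparagine synthetase Asns (log2FC -2.34) and Chac1 (log2FC -2.59). Of primitive streak genes, 1 of 21 rose and 6 fell (camera adjusted p = 0.00810 but p_est = 0.586). Of 24 lists, 10 passed camera, and 5 with an estimated correlation. Limma called 1899 genes, 752 higher and 1147 lower in LC d3ag3, and 874 and 1216 with median-ratio scaling. Both groups lie in the same library set. With 2 libraries each, the spread rests on the fit over all groups. With these groups alone, and so without the line block, 4505 genes were called.

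The comparison of SC d3 with LC d3 set PGCLC of different labels side by side (n = 2 and 2). Hox genes were higher in SC d3, with Hoxd9 (29.9±2.50 against 0.0885±0.00356 TPM, log2FC 4.83±0.57, adjusted p = 4.22e-06) (ENSRNOG00000001580.6), Hoxc8 (7.18±2.77 against 0.103±0.112 TPM, log2FC 2.85±0.41, adjusted p = 5.87e-05), Hoxc9 (6.10±0.173 TPM, listed at 0 in every LC d3 library) and Hoxd10 (5.71±0.111 TPM, listed at 0 in every LC d3 library). From the glycolysis list the mitochondrial Bnip3 (270.4±96.6 against 34.8±9.84 TPM, log2FC 2.90±0.78, adjusted p = 0.0150), the pyruvate dehydrogenase kinase Pdk1 (13.1±6.12 against 1.01±0.0652 TPM, log2FC 2.73±0.73, adjusted p = 0.0151) and Tpi1 (264±58.5 against 47.8±4.32 TPM, log2FC 2.43±0.38, adjusted p = 1.49e-04) rose. The germ cell regulators did not pass the test, with Tfap2c (188±44.9 against 146±0.0184 TPM, adjusted p = 0.840), Prdm1 (32.6±0.0721 against 20.2±1.20 TPM, adjusted p = 0.326), Prdm14 (24.8±1.16 against 21.5±3.20 TPM, adjusted p = 0.803), Nanos3 (82.7±20.5 against 47.8±3.61 TPM, adjusted p = 0.296) and Kit (92.3±14 against 88.6±1.68 TPM, adjusted p = 0.977). Pou5f1 (293±25.5 against 97.7±5.48 TPM, log2FC 1.57±0.31, adjusted p = 0.00129) rose, and the calls of Sox2 (log2FC 0.80) and Nanog (log2FC 1.23) ended with median-ratio scaling (adjusted p = 0.0949 and 0.0840).

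The largest increases were those of Rps6, of Grb10 (98.3±15.4 against 0.634±0.108 TPM), of Vstm2l (52.9±13.2 against 0.717±0.0492 TPM), of the phosphohydrolase Nudt11 (132±10.7 against 3.40±1.08 TPM) and of Hoxd9, and the largest decreases were those of Rps4y2 (2.75±1.68 against 113±12.8 TPM), Gabpb1l (listed at 0 in every SC d3 library, 23.1±2.83 TPM in LC d3), Dppa4 (0.868±0.864 against 29.9±0.345 TPM), the X-linked MAGE family member Mageb4 (listed at 0 in every SC d3 library, 12.8±0.0795 TPM in LC d3) and the testis ribosomal paralogue Rpl10l (0.556±0.510 against 12.5±0.936 TPM).

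Of the Hox list, 11 of 15 tested members rose and 0 fell (14 and 0 adjusted over the list alone), with camera adjusted p = 1.63e-16. Of the glycolysis list, 12 of 17 tested members rose and 0 fell (13 and 0 adjusted over the list alone). Its members had camera adjusted p = 7.94e-10 but p_est = 0.199. Of the cell cycle list, 7 of 20 tested members rose and 0 fell (11 and 0 adjusted over the list alone). The test for the list gave camera adjusted p = 2.87e-04 but p_est = 0.263: the replication genes Mcm2 (log2FC 1.08) and Cdc6 (log2FC 1.03) and the kinase Cdk1 (log2FC 1.25) rose, and so did Cdkn1c (log2FC 4.44), an inhibitor of cell division. Activin and Nodal targets had camera adjusted p = 0.0363 but p_est = 0.199. In it 4 of 12 rose and 0 fell (6 and 0 adjusted over the list alone), led by Lefty2 (log2FC 3.52), and 1 rose and 0 fell with median-ratio scaling. The DNA methylation list had camera adjusted p = 0.0457 but p_est = 0.537. In it 7 of 15 rose and 0 fell (8 and 0 adjusted over the list alone), with Ehmt1 (log2FC 1.02) and the maintenance methyltransferase Dnmt1 (log2FC 0.89) among them, and 3 rose and 0 fell with median-ratio scaling.

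Of 24 lists, 8 passed camera, and 1 with an estimated correlation. Limma called 1722 genes, 1455 higher and 267 lower in SC d3 (84.5% higher). Mitochondrial transcripts took 7.59±0.261% of the total TPM in SC d3 against 12.0±0.559% in LC d3, and the 10 most abundant genes 15.6±0.283% against 22.0±0.276%. This comparison crosses the library sets, and median-ratio scaling gave 767 higher and 475 lower (61.8% higher), with the median of all genes at 0.03 instead of 0.18. With these groups alone and no line block 2854 genes were called.

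The comparison of LCSC d3 with LC d3 again set PGCLC groups side by side (n = 2 and 2). Genes of the glycolysis list were higher in LCSC d3, with Pdk1 (22.0±6.33 against 1.01±0.0652 TPM, log2FC 3.48±0.73, adjusted p = 0.00475) (ENSRNOG00000001517.6), Bnip3 (279.9±84.5 against 34.8±9.84 TPM, log2FC 2.97±0.78, adjusted p = 0.0208), Tpi1 (260.1±40.7 against 47.8±4.32 TPM, log2FC 2.42±0.38, adjusted p = 4.51e-04) and Hk2 (24.7±7.29 against 3.97±0.187 TPM, log2FC 2.34±0.39, adjusted p = 5.99e-04). Pou5f1 (376±10.1 against 97.7±5.48 TPM, log2FC 1.93±0.31, adjusted p = 4.55e-04) and OTX2 (4.88±0.507 against 0.690±0.470 TPM, log2FC 1.82±0.43, adjusted p = 0.0115) rose, and the calls of Bnip3 and Uhrf1 (log2FC 2.18) ended with median-ratio scaling (adjusted p = 0.0624 and 0.0620). The germ cell regulators did not pass the test, with Tfap2c (204±20.9 against 146±0.0184 TPM, adjusted p = 0.757), Prdm1 (26.9±0.139 against 20.2±1.20 TPM, adjusted p = 0.620) and Nanos3 (34.0±8.87 against 47.8±3.61 TPM, adjusted p = 0.553).

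The strongest increases besides Pdk1 were those of Rps6, Sdhaf1 (18.7±2.44 against 0 to 0.708 TPM per library), Vstm2l (20.9±6.20 against 0.717±0.0492 TPM) and Nudt11 (50.3±3.27 against 3.40±1.08 TPM). The largest decreases were those of the vasohibin Vash2 (5.89±1.13 against 44.2±3.83 TPM), Pcp4l1 (5.39±3.21 against 41.5±29.4 TPM), Rpl10l (2.13±2.42 against 12.5±0.936 TPM), the channel subunit Cacng2 (12.7±1.90 against 61.6±3.39 TPM) and Mageb4 (2.46±1.75 against 12.8±0.0795 TPM). Of the glycolysis list, 12 of 17 tested members rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 2.38e-16. Of the Hox list, 6 of 15 tested members rose and 0 fell, led by Hoxd9 (log2FC 3.26) and Hoxd8 (log2FC 1.89). The test gave camera adjusted p = 9.60e-06 but p_est = 0.114. The formative and primed list had camera adjusted p = 0.00843 but p_est = 0.133. In it 6 of 20 rose and 0 fell (9 and 0 adjusted over the list alone), with Zic5 (log2FC 1.38) among them, and 2 rose and 0 fell with median-ratio scaling.

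Of the cell cycle list, 5 of 20 tested members rose and 0 fell. This list had camera adjusted p = 0.0384 but p_est = 0.603, and Mcm2 (log2FC 0.87), Cdc6 (log2FC 0.83), the topoisomerase Top2a (log2FC 0.72) and Cdk1 (log2FC 0.68) were higher, but none of these 4 calls held with median-ratio scaling (adjusted p = 0.0766, 0.0663, 0.133 and 0.119), where 0 rose and 0 fell. Wnt targets had camera adjusted p = 0.0394 in the direction of a fall but p_est = 0.480. In it 0 of 12 rose and 1 fell, the latter being Notum (log2FC -0.93).

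Of 24 lists, 7 passed camera, and 1 with an estimated correlation. Limma called 1079 genes, 963 higher and 116 lower in LCSC d3 (89.2% higher). In LCSC d3 mitochondrial transcripts took 7.54±0.590% and the 10 most abundant genes 15.2±0.721% of the total TPM, below LC d3 as in SC d3. This comparison crosses the library sets, and median-ratio scaling gave 224 higher and 165 lower (57.6% higher), with the median of all genes at 0.04 instead of 0.24. The count fell to 550 without LC d3 replicate 2 and to 647 without LCSC d3 replicate 1, and with these groups alone and no line block it was 3836.

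The comparison of LCSC d3 with SC d3 found few differences (n = 2 and 2). The pluripotency-associated Dppa4 (31.8±7.35 against 0.868±0.864 TPM, log2FC 4.20±0.34, adjusted p = 2.68e-08) (ENSRNOG00000025404.5), Rps4y2 and the ADP-ribosyltransferase family member Parp12 (24.0±2.23 against 0.965±0.139 TPM, log2FC 3.67±0.29, adjusted p = 1.96e-08) were higher in LCSC d3. The imprinted adaptor Grb10 (1.46±0.562 against 98.3±15.4 TPM, log2FC -5.35±0.22, adjusted p = 6.62e-14) (ENSRNOG00000004290.7) and the signal peptide peptidase Hm13 (8.80±0.886 against 53.8±1.72 TPM, log2FC -2.49±0.23, adjusted p = 2.97e-07) were lower. The Hox genes Hoxc8 (1.40±1.54 against 7.18±2.77 TPM, log2FC -1.90±0.41, adjusted p = 0.0294) and Hoxd10 (1.76±1.16 against 5.71±0.111 TPM, log2FC -1.35±0.28, adjusted p = 0.0230) were lower as well. The germ cell regulators did not pass the test, with Tfap2c (204±20.9 against 188±44.9 TPM, adjusted p = 1.00), Prdm1 (26.9±0.139 against 32.6±0.0721 TPM, adjusted p = 1.00) and Nanos3 (34.0±8.87 against 82.7±20.5 TPM, adjusted p = 0.297), nor did Pou5f1 (376±10.1 against 293±25.5 TPM, adjusted p = 0.945) and Nanog (83.6±9.94 against 138±28.8 TPM, adjusted p = 0.683).

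The other large increases were those of Rps4y2 (59.1±24.6 against 2.75±1.68 TPM), Gtpbp6 (33.6±1.30 against 4.64±1.03 TPM) and Basp1 (46.7±0.573 against 10.2±5.50 TPM). The other large decreases were those of Ppp1r14c (15.8±8.48 against 54.9±10.3 TPM), the zinc finger gene Zfp184 (71.2±7.34 against 157±33.3 TPM) and the growth factor midkine, Mdk (457±20.6 against 976±174 TPM), where the call of Ppp1r14c ended with median-ratio scaling (adjusted p = 0.0510). Of the Hox list, 0 of 15 tested members rose and 2 fell (0 and 8 adjusted over the list alone), with camera adjusted p = 5.45e-12. Of primitive streak genes 0 of 21 rose and 0 fell, with camera adjusted p = 8.70e-05 in the direction of a fall but p_est = 0.329. Activin and Nodal targets had camera adjusted p = 0.00683 in the direction of a fall but p_est = 0.0555, and 0 of 12 rose and 0 fell. The p53 and apoptosis list had camera adjusted p = 0.00227 in the direction of a rise but p_est = 0.215, and 0 of 13 rose and 0 fell (1 and 0 adjusted over the list alone).

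Of 24 lists, 6 passed camera, and 1 with an estimated correlation. Limma called 91 genes, 48 higher and 43 lower in LCSC d3, with both groups in the same library set. The count was 162 without LCSC d3 replicate 2 and 197 without SC d3 replicate 2, and with these groups alone and no line block limma called 0 genes, where 2249 had an unadjusted p under 0.05 and the smallest adjusted p was 0.106.

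**Figure D3:**
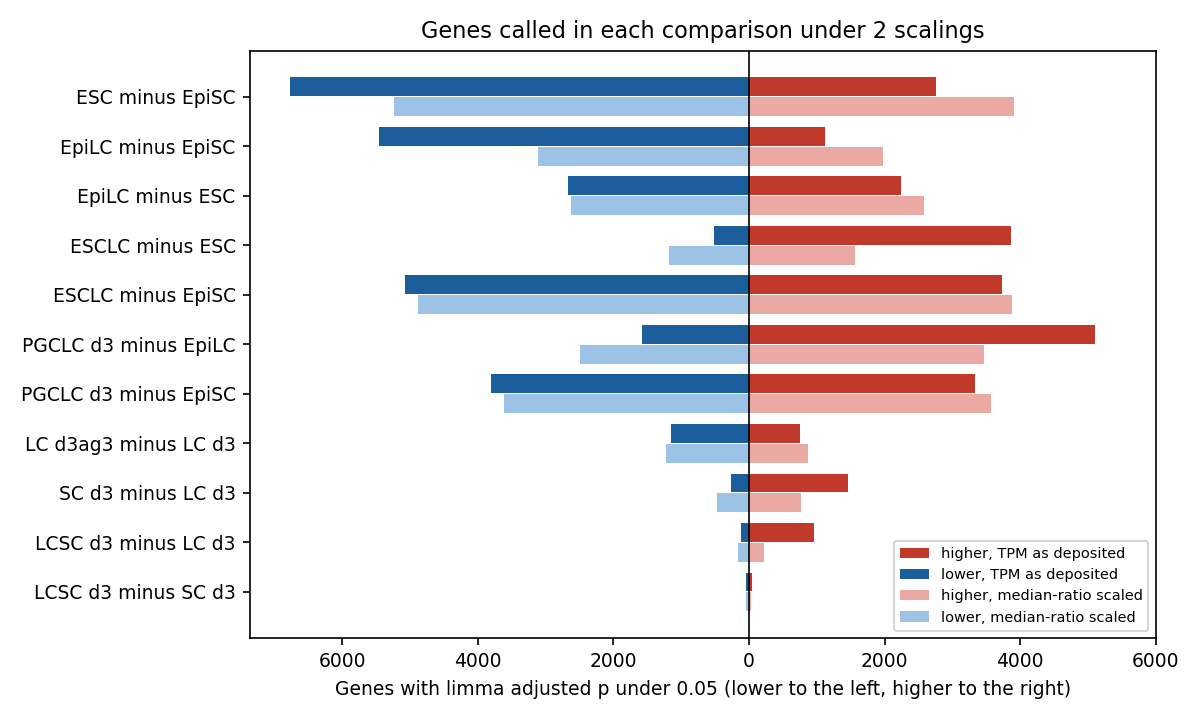
Bars give the number of genes with a limma adjusted p under 0.05 (x axis) in each comparison (y axis), higher to the right and lower to the left, from the TPM as deposited (dark) and after median-ratio scaling (light). For ESCLC minus ESC the bars hold 3869 higher and 511 lower genes as deposited, and 1569 and 1185 after scaling.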

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

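Each of 47 measures was examined in the 3 groups of 4 to 8 libraries, and in 11 of 141 such tests a library lay far from the others of its group, where chance flags about 1 in 20. In this part, tests on splits of single libraries, mitochondrial and ribosomal protein genes and leftover ESC-like cells were planned before their result was seen. The others were chosen as tests only after.

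Library EpiSC_PV_2 had 12300 genes at 1 TPM or more, against 11490 to 11820 in the other EpiSC libraries. The following are on the log2(TPM + 1) scale. In ESCLC_P2_2, Nanog stood at 9.45 against 9.18 to 9.21, and the mean of the Wnt target list at 1.28 against 1.52 to 1.55. In EpiSC_WT1_1, Esrrb stood at 0.79 (others 0 to 0.21), Prdm1 at 1.64 (others 0.04 to 0.65) and Tfap2c at 2.96 (others 0.34 to 1.55). Prdm1 stood at 0.0179 in ESCLC_P2_1 and was listed at 0 in the other ESCLC libraries. In EpiSC_N3TAG_1, Dppa3 stood at 0.41 while listed at 0 in the others, and the mean of the DNA methylation list stood at 4.52 against 4.36 to 4.43. That mean was lowest in ESC_WT_1, at 4.20 against 4.40 to 4.51. The mean of the oxidative phosphorylation list was highest in ESC_WT_2, at 7.51 against 7.24 to 7.33.

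Of 100 drawn library splits, only the real one called as many genes in 4 comparisons. With whole lines moved, 1 of 35 splits called as many for ESC against EpiSC. The real one called 9271 genes here (9525 above), the highest other 2 by library and 6465 by line. Mixing groups that differ widens the spread, so this cannot exclude chance. The labels name no lines for ESCLC and PGCLC. With each P number and PGCLC group taken as a line, 1 of 35 splits called as many for ESCLC against EpiSC (8785, highest other 3 and 4828) and for PGCLC d3 against EpiSC (6255, highest other 1 and 3751). For ESCLC against ESC (3774, others at most 113 and 0) such lines make 10 splits, too few for a share under 0.05.

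Higher calls far outnumbered lower calls between ESCLC and ESC (88.3%). Removing mitochondrial and ribosomal protein genes left the share at 84.08%, which excludes these as the sole source. A different share of the total TPM taken by a few abundant transcripts cannot be told apart from a true rise of many genes. Median-ratio scaling gave 56.97%, but it centres most genes by construction, and removing the 100 most abundant genes lowered it only in part, to 77.44%. Among the 5 comparisons across the library sets defined by Rps6, the smallest distance from an even split was 21 points, and the largest among the 4 within a set was 10.4. Whether the sets differ by preparation or by source is confounded with the groups.

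Rps6 was near 0 in 12 libraries and high in 16. Cell kind cannot be told apart from other causes, as no group was mixed, although the lowest ESCLC library stood at 270 TPM while ESC stayed near 0. Reads given to another copy cannot be told apart from other causes. Without overlap, 259 genes split the libraries as Rps6 did and 14 the opposite way, none of these 14 named as a copy of Rps6. A variant at this locus cannot be told apart either, as only 3 genes, Rps6, LOC108348142 and LOC100911515, split the libraries by more than 3 times in either direction at 5 TPM or more. No other biological explanation was tested.

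Grb10 and Hm13 were high, and Dppa4 and Rps4y2 low, in the 10 libraries of EpiSC and SC d3 but not in LCSC d3. ESC-like cells left in LCSC d3 are excluded as the source: 33 other genes abundant in ESCLC and scarce in SC d3 stood in LCSC d3 at a median of 0.742% of their ESCLC level (quartiles 0.181 and 1.55), against 15.6% for Rps4y2 and 40.6% for Dppa4. For Rps4y2, reads shared with a copy may contribute, since it stood at 273 TPM or more in the ESC_WT libraries, where Eif2s3y stood at no more than 0.528 TPM. A difference in the cells from which these groups were derived stays open as untested.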

How the results depend on the processing

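Median-ratio scaling of the position and the PGCLC comparisons with fewer groups were chosen only after the data were seen, and the other alternatives before. Of 960 results for named genes, 883 stayed on the same side of the threshold with median-ratio scaling, 75 lost and 2 gained their call, and with a pseudocount of 0.1 these were 901, 55 and 4. The cause was not tested for any change below unless the setting itself gives it.

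LCSC d3 against SC d3 (91 genes as reported) moved most: 42 with a pseudocount of 0.1, 161 with 5, 225 without a filter, 41 with a filter of 5 TPM, 532 without the line block, and 0 by limma with only the groups compared and no line block (2249 at an unadjusted p under 0.05). LCSC d3 against LC d3 (1079) gave 389 with median-ratio scaling, 441 with quantile normalization, 671 without mitochondrial and ribosomal protein genes, 3100 without the line block and 3836 with only the groups compared and no line block. ESCLC against ESC (4380) gave 2754 and 2493 with the scalings. LC d3ag3 against LC d3 (1899) gave 3604 and 4505, and SC d3 against LC d3 (1722) 3478 and 2854, without the line block, first over all groups and then with only the groups compared.

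Leaving out 1 library or line gave 8911 to 9523 genes for ESC against EpiSC, 5543 to 6676 genes for EpiLC against EpiSC, 4030 to 4794 genes for EpiLC against ESC, 3638 to 4048 genes for ESCLC against ESC, 8189 to 8886 genes for ESCLC against EpiSC, 5681 to 6812 genes for PGCLC d3 against EpiLC, 6529 to 7309 genes for PGCLC d3 against EpiSC, 1377 to 1694 genes for LC d3ag3 against LC d3, 1185 to 1640 genes for SC d3 against LC d3, 550 to 930 genes for LCSC d3 against LC d3 and 61 to 197 genes for LCSC d3 against SC d3. Where this left a group with 1 library, as in every comparison between PGCLC groups, that library is assumed to vary like the other groups.

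The number of lists passing camera fell with an estimated correlation: ESC against EpiSC 6 to 2, EpiLC against EpiSC 6 to 2, EpiLC against ESC 4 to 2, ESCLC against ESC 3 to 0, ESCLC against EpiSC 8 to 2, PGCLC d3 against EpiLC 11 to 5, PGCLC d3 against EpiSC 11 to 6, LC d3ag3 against LC d3 10 to 5, SC d3 against LC d3 8 to 1, LCSC d3 against LC d3 7 to 1 and LCSC d3 against SC d3 6 to 1. With fry, which tests a balance in 1 direction, the numbers were 20 for ESC against EpiSC, 12 for EpiLC against EpiSC, 16 for EpiLC against ESC, 9 for ESCLC against ESC, 17 for ESCLC against EpiSC, 19 for PGCLC d3 against EpiLC, 20 for PGCLC d3 against EpiSC and 3 for LCSC d3 against SC d3. With median-ratio scaling 4 lists passed for LCSC d3 against LC d3. Fry reversed the direction of the fibroblast and feeder list (adjusted p = 0.0295) and of the gonadal somatic list (adjusted p = 0.00713) for ESC against EpiSC.

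With LC d3 as the only PGCLC group, Hoxd9 (log2FC -0.053, adjusted p = 0.971) and Bnip3 (log2FC -0.27, adjusted p = 0.853) reversed against EpiLC, and with LCSC d3 and SC d3 as the only groups Pou5f1 (log2FC 0.11, adjusted p = 0.704) reversed against EpiSC. The position of ESCLC was 0.996 over genes with a fold of at least 4, 0.980 with median-ratio scaling, 0.931 with a pseudocount of 0.1, and 0.942 to 0.955 without 1 ESCLC library.

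A replicate block gave 9473 genes for ESC against EpiSC, 6423 for EpiLC against EpiSC and 4814 for EpiLC against ESC. For ESCLC it gave 3426 against ESC and 7114 against EpiSC. For PGCLC d3 it gave 6541 against EpiLC and 7041 against EpiSC. Against LC d3 it gave 1816 for LC d3ag3, 1608 for SC d3 and 955 for LCSC d3. LCSC d3 against SC d3 gave 70. Each was within 1.5 times of the reported count, and 39 of 960 results for named genes lost their call. Libraries that share a number did not deviate together (r from -0.072 to 0.088, median 0.011, over 78 pairs of 13 lines), so they share only a number and the block tests no pairing.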

Other observations

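Igf2, an imprinted growth factor gene, stood at 8.95 and 5.51 TPM in the SC d3 libraries and at no more than 1.5 TPM in any other library. Snrpn, another imprinted gene, stood at 297 to 386 TPM in EpiSC and EpiLC against 35.4 to 48.4 TPM in ESC and 65.6 to 77.5 TPM in ESCLC. Gdf3, a TGF-beta family ligand, stood at 143 to 189 TPM in ESC and 158 to 206 TPM in ESCLC, at 12.8 and 13.2 TPM in EpiLC and at no more than 0.204 TPM in EpiSC. These 3 genes were chosen after their values were seen, and no test was made of them here.

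Of the Y-linked genes, Eif2s3y stood at 0.069 and 0.528 TPM in the ESC_WT libraries and at 80.5 to 128 TPM in the other 26, while Ddx3y stood at 13.6 and 13.3 TPM in ESC_WT and was listed at 0 in all 8 EpiSC libraries. Among genes often used for reference, Actb stood between 1340.0 and 4320.0 TPM and Tbp between 24.3 and 61.6 TPM.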
